A study of Mus musculus with 10 samples.

How the data were processed

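The deposited values were read counts per gene and library. According to the authors' notes, reads were aligned to mm10 with STAR and counted with HTSeq, with no versions or strand setting given. The counts were used as deposited. Genes were matched by Ensembl identifier to GENCODE M21, whose build may not be the one the authors used. The table held 22165 identifiers, of which 420 had no symbol and 7409 had 0 counts in all 10 libraries.

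Counts were scaled with TMM factors and filtered with filterByExpr (minimum count 10, minimum total 15) in edgeR 4.0.16 under R 4.3.3, which left 11614 genes. A quasi-likelihood model with 4 group means and robust dispersion left 6 residual degrees of freedom, with a common biological coefficient of variation of 28.4%. The 7 contrasts were knockout against wild type after IL-4, under basal conditions and averaged, IL-4 against basal in wild type, in knockout and averaged, and the interaction, which is the IL-4 effect in knockout minus that in wild type. Tests were two-sided, and genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Values after log2 are knockout minus wild type or IL-4 minus basal, with ± for the standard error, and ± after a CPM mean is the SD between libraries.

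Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists with at least 3 tested members within a contrast, and again with the correlation estimated per list. The fry test served as a companion that asks whether the genes of a list move, on balance, one way. Of the 36 lists, 34 could be tested: alternative activation, S phase and DNA replication, G2 and mitosis, efferocytosis receptors and bridging molecules, actin remodelling and phagocytic cup, glutamine use and transamination, malate-aspartate shuttle and malic enzymes, glutathione and thioredoxin and NRF2 targets, nuclear-encoded respiratory complexes I to IV, ATP synthase, mitochondrially encoded transcripts, TCA cycle, glycolysis, HIF1 and hypoxia targets, fatty acid oxidation and peroxisome, cholesterol synthesis and SREBP2 targets, LXR targets and cholesterol efflux, ATF4 and amino-acid response, endoplasmic reticulum stress, lysosome and autophagy, interferon-stimulated genes, NF-kB and inflammatory cytokines, large peritoneal macrophage markers, small peritoneal macrophage and monocyte and dendritic cell markers, B cell markers, T and NK cell markers, neutrophil markers, eosinophil markers, mast cell and basophil markers, mesothelial and fibroblast markers, erythroid markers, immediate early and handling stress, p53 targets and apoptosis, and cytosolic ribosomal proteins. The list of nuclear-retained and RNA-quality transcripts had 2 tested members and the list of sex-linked transcripts 0. Each list count gives members past the threshold over all genes, with the numbers that passed when p was adjusted over the list alone in parentheses as higher and lower within the list.

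Genes were named by a fixed rule: Lyz2 in every contrast, then in each contrast the 10 largest rises and falls among passing genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of the groups compared (overlap was not asked of averages and the interaction), then up to 4 passing members of each list with the smallest p, or 2 given as values where none passed. Chance alone parts 2 libraries from 2 in 33.3% of splits, 2 libraries from 3 in 20% of splits and 3 libraries from 3 in 10% of splits. For the number of called genes, fits without 1 library are given where the total or either direction moved by more than 1.5 times, the share of higher genes by more than 10 percentage points, or the majority turned. The lists, the tests, the rule and most other settings were chosen before the data were examined. Among genes of the rule, those that kept their call in every fit without 1 library were preferred, a preference set after those fits were seen. They were 279 of 547 called values over the 7 contrasts, and 60 of 83 list calls were kept in every such fit. A gene that the rule also named is not reported here. Where such a fit left 1 library in a group, that library was assumed to vary like the other groups.

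A fold against a group with no counts is given as a bound, with the group set to a floor of 3 counts over its libraries. Such floors cover counting error alone. A list median is given with those genes at their bounds where that changes it. In simulated counts with the depth and spread of these libraries, the test recovered 24.2% of 2-fold and 82.8% of 4-fold changes in the genotype contrast after IL-4, 14.1% and 69.0% under basal conditions, and 1.01% and 43.4% for the interaction. With no simulated effect, at most 1 gene and 1 list were called in a contrast. Correlation between genes was not matched, so list calls stay unchecked. With effects, 2.22% to 9.18% of calls per contrast were unchanged genes (aim 5%). Other tools were DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.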

Results

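Peritoneal cavity macrophages of C57BL/6 mice were sorted on CD64, ICAM-2 and CD115, surface proteins of macrophages and monocytes. Mice with a floxed allele are called wild type here, and mice that also carried LysM-Cre, a Cre recombinase driven by the Lyz2 locus in myeloid cells, are called knockout. Each comparison of genotypes thus also compares mice with and without Cre. The mice had received saline (basal) or IL-4 complexed with an antibody to IL-4, which prolongs the action of the cytokine, and were lavaged with 5 ml of PBS 36 hours later. IL-4 drives the alternative activation of tissue macrophages and makes resident ones divide. The series addresses the clearance of dying cells, redox balance and respiration. Polyadenylated RNA was sequenced in 10 libraries, 2 in each basal group and 3 in each IL-4 group. The labels do not say whether replicates were separate animals, so each p measures only the spread between these samples. Counted reads ranged from 8762403 to 15024073 per library, and 11614 of 22165 genes were tested. The first principal component, with 27.6% of the variance, placed the basal libraries at 38.1 to 48.5 and the IL-4 libraries at -41.7 to -15.7. On the next component (17.7%), the knockout basal libraries lay at 42.4 to 44.1 and the wild-type basal libraries at -47.2 to -46.3, with the IL-4 libraries at -1.69 to 5.34.

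**Figure D1:**
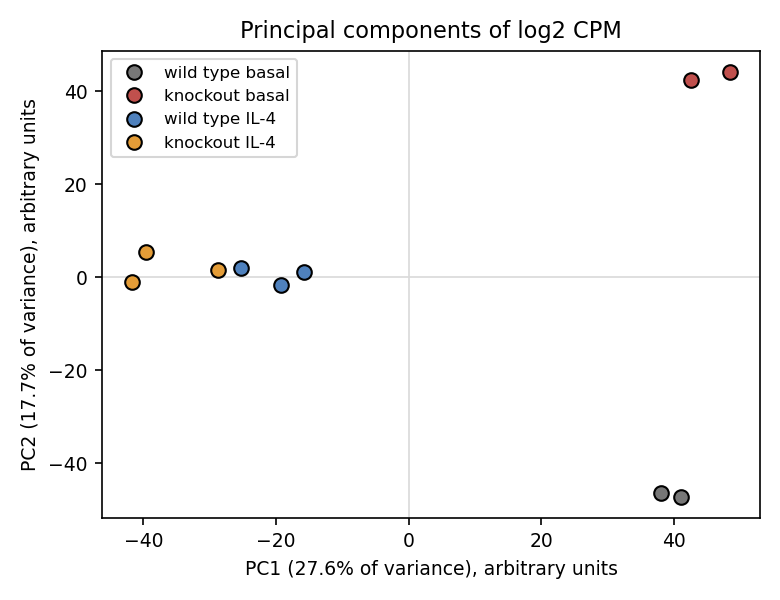
Principal components of log2 CPM across the tested genes, with 1 point per library coloured by group, and axes in component units with the percentage of variance. Basal and IL-4 libraries separate on the first axis (27.6%), and the knockout basal libraries (42.4 to 44.1) lie apart from the wild-type basal libraries (-47.2 to -46.3) on the other axis.

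Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321, mm10 with GENCODE M21), the lysozyme gene that carries the Cre driver, was 3.69-fold lower in knockout than wild-type basal libraries (6169.6 ± 4958 against 22751 ± 1200.1 CPM, log2 -1.88 ± 0.42, adjusted p = 0.0249). The knockout basal libraries held 2664 and 9675 CPM. After IL-4 the means were 3482 and 6472 CPM (log2 -0.89 ± 0.34, adjusted p = 0.249). The averaged genotype effect was log2 -1.39 ± 0.27, adjusted p = 0.0131, and IL-4 lowered Lyz2 in wild type (log2 -1.81 ± 0.37, adjusted p = 0.0123) but not past the threshold in knockout (log2 -0.83 ± 0.37, adjusted p = 0.203), with an interaction of log2 0.99 ± 0.53, adjusted p = 0.405. Lyz1, a close paralog that can share reads with Lyz2, went the other way and was 7.52-fold higher in knockout basal libraries (log2 2.91 ± 0.28, adjusted p = 3.94e-05). Lyz2 lost its call between basal genotypes without wild-type basal replicate 2 (adjusted p = 0.145) or replicate 1 (0.124). Lyz2 lost its call in the averaged genotype effect without wild-type basal replicate 2 (adjusted p = 0.0702) or replicate 1 (0.0646). Lyz2 lost its call for IL-4 in wild type without wild-type basal replicate 1 (adjusted p = 0.103) or replicate 2 (0.103).

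After IL-4, Igf1, the gene of insulin-like growth factor 1, was 3.67-fold higher in knockout (616 ± 34.7 against 168 ± 10.9 CPM, n = 3 libraries each, log2 1.88 ± 0.21, adjusted p = 3.75e-04). Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), a marker of dividing cells, was 4.15-fold higher (log2 2.05 ± 0.39, adjusted p = 0.0282). Cacnb4, a calcium channel subunit (log2 1.83 ± 0.26, adjusted p = 0.00368), and Cd200r3, a receptor of the CD200 receptor family (log2 1.62 ± 0.25, adjusted p = 0.00537), were also higher. Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), a chitinase-like lectin that IL-4 induces, was 4.26-fold lower in knockout (402 ± 96.8 against 1709.9 ± 262 CPM, log2 -2.09 ± 0.21, adjusted p = 1.18e-04). Clec10a, a lectin of alternatively activated macrophages, was 3.25-fold lower (log2 -1.70 ± 0.22, adjusted p = 0.00245). Crispld2, a secreted protein gene, was 14.8-fold lower (log2 -3.89 ± 0.34, adjusted p = 3.21e-05), and Fkbp5, a co-chaperone gene that glucocorticoids induce, 5.54-fold lower (log2 -2.47 ± 0.38, adjusted p = 0.00666). The test passed 41 genes as higher and 55 as lower in knockout, 96 of 11614, and 1673 had an unadjusted p under 0.05. There were 8 higher and 13 lower without wild-type IL-4 replicate 1, 14 and 26 without wild-type IL-4 replicate 3, 24 and 26 without knockout IL-4 replicate 3, 20 and 34 without wild-type IL-4 replicate 2, 59 and 50 without knockout IL-4 replicate 2 and 74 and 47 without knockout IL-4 replicate 1. The majority turned without knockout IL-4 replicate 1 or knockout IL-4 replicate 2, and with the DESeq2 test (185 and 181) and no filter (290 and 215). Mki67 lost its call without wild-type IL-4 replicate 1 (adjusted p = 0.141), replicate 3 (0.0974) or replicate 2 (0.0599).

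The alternative activation list moved both ways, as 2 of 35 members rose, 3 fell and 30 did not pass (6 higher, 6 lower within the list). Beside the falls of Chil3 and Clec10a, Tgm2, a protein cross-linking enzyme, fell (log2 -2.37 ± 0.39, adjusted p = 0.00793), while Ccl24, an eosinophil-attracting chemokine, rose (log2 0.96 ± 0.20, adjusted p = 0.0334). The list as a whole was not called (median log2 0.07, camera adjusted p = 0.577). In the G2 and mitosis list 1 of 43 members rose, 0 fell and 42 did not pass (9 higher, 0 lower within the list). The mitosis list had a median log2 of 0.75 (camera adjusted p = 2.93e-12, or 0.254 with an estimated correlation). 42 members had a positive value. In the S phase list 0 of 38 members passed (4 higher, 0 lower within the list). The S phase list had a median log2 of 0.40 (camera adjusted p = 9.21e-04, or 0.426 with an estimated correlation). Among genes of the endoplasmic reticulum stress response 0 of 26 members rose, 2 fell and 24 did not pass (1 higher, 10 lower within the list). The list had a median log2 of -0.43 (camera adjusted p = 7.32e-06, or 0.0513 with an estimated correlation). Manf, a secreted stress-induced factor, fell 2.23-fold (log2 -1.16 ± 0.19, adjusted p = 0.00801). Tgm2 lost its call without wild-type IL-4 replicate 1 (adjusted p = 0.0774), as did Manf (0.0774). Ccl24 lost its call in 5 of the 10 fits without 1 library (adjusted p up to 0.160 without wild-type IL-4 replicate 3).

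Receptors and bridging molecules of efferocytosis, the uptake of dying cells, were not called after IL-4, as 0 of 32 members passed (0 higher, 2 lower within the list). The efferocytosis list had a median log2 of -0.20 (camera adjusted p = 0.0688). The scavenger receptors Marco (log2 -1.52 ± 0.38, adjusted p = 0.0895) and Stab1 (log2 -0.80 ± 0.23, adjusted p = 0.111) had the smallest p. In the glutamine use and transamination list 0 of 34 members passed (0 higher, 0 lower within the list). The glutamine list had a median log2 of -0.06 (camera adjusted p = 0.492). Slc7a5, an amino-acid exchanger, had log2 -1.78 ± 0.61, adjusted p = 0.194. In the glutathione, thioredoxin and NRF2 list 0 of 41 members passed (0 higher, 0 lower within the list). The glutathione list had a median log2 of -0.21 (camera adjusted p = 0.0223, or 0.619 with an estimated correlation). In the list of nuclear-encoded respiratory complexes 0 of 61 members passed (0 higher, 0 lower within the list). The respiratory complex list had a median log2 of -0.26 (camera adjusted p = 0.00129, or 0.678 with an estimated correlation). Cyc1 of complex III had log2 -0.81 ± 0.23, adjusted p = 0.110. Mitochondrially encoded transcripts (median log2 0.05, camera adjusted p = 0.577) and the TCA cycle (median log2 -0.12, camera adjusted p = 0.427) were not called. Nor were the malate-aspartate shuttle (median log2 0.12, camera adjusted p = 0.954) and glycolysis (median log2 -0.16, camera adjusted p = 0.169). The glutathione list lost its call without knockout IL-4 replicate 3 (camera adjusted p = 0.282) or wild-type IL-4 replicate 1 (0.186). The respiratory complex list lost its call without wild-type IL-4 replicate 1 (camera adjusted p = 0.139) or knockout IL-4 replicate 3 (0.111).

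Between genotypes after IL-4, in the ribosomal protein list 0 of 69 members passed (1 higher, 0 lower within the list). The ribosomal list had a median log2 of -0.33 (camera adjusted p = 7.32e-06, or 0.551 with an estimated correlation). Neutrophil markers summed to 281 ± 32.0 CPM in knockout and 433 ± 38.8 CPM in wild type, and 0 of 13 members rose, 3 fell and 10 did not pass (0 higher, 5 lower within the list). The neutrophil list had a median log2 of -0.98 (camera adjusted p = 1.45e-07, or 0.152 with an estimated correlation). S100a8, part of the calprotectin complex, fell (log2 -1.58 ± 0.30, adjusted p = 0.0189). For T and NK cell markers 0 of 22 members passed (0 higher, 0 lower within the list). The T and NK cell list had a median log2 of -0.56 (camera adjusted p = 0.0354, or 0.551 with an estimated correlation). B cell markers were not called (median log2 -0.15, camera adjusted p = 0.639). Among markers of large peritoneal macrophages, the resident population, 2 of 32 members rose, 3 fell and 27 did not pass (3 higher, 5 lower within the list): Cxcl13, a B cell attracting chemokine, fell from 418 ± 70.7 to 49.7 ± 32.8 CPM (log2 -3.08 ± 0.39, adjusted p = 0.00265), while Selp, P-selectin, rose (log2 1.19 ± 0.19, adjusted p = 0.00727). Saa3, an acute-phase serum amyloid gene, fell 4.61-fold (log2 -2.20 ± 0.28, adjusted p = 0.00245). None of the 8 lists called in this comparison kept the call with an estimated correlation. S100a8 lost its call without wild-type IL-4 replicate 1 (adjusted p = 0.112), replicate 3 (0.0848) or knockout IL-4 replicate 3 (0.0731). The T and NK cell list lost its call in 9 of the 10 fits without 1 library (camera adjusted p up to 0.282 without knockout IL-4 replicate 3).

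Without IL-4, the knockout libraries held far more RNA of B cell genes than the wild-type libraries. Ebf1 (log2 3.51 ± 0.30, adjusted p = 1.44e-05) and Pax5 (log2 4.17 ± 0.39, adjusted p = 3.71e-05), transcription factors of the B lineage, were 11.4-fold and 18.1-fold higher (n = 2 libraries each). Siglecg, an inhibitory receptor of B cells, was 11.9-fold higher (log2 3.57 ± 0.30, adjusted p = 1.44e-05). In the B cell marker list 19 of 22 members rose, 0 fell and 3 did not pass (20 higher, 0 lower within the list). The B cell list had a median log2 of 3.03 (camera adjusted p = 2.02e-64, or 0.00280 with an estimated correlation). The markers summed to 2602 ± 273 CPM in knockout and 471 ± 152 CPM in wild type. Of mast cell genes, Cma1, a chymase (log2 2.83 ± 0.47, adjusted p = 0.00260), and Tpsb2, a tryptase (log2 2.36 ± 0.38, adjusted p = 0.00181), rose. Of mast cell and basophil markers 4 of 11 members rose, 0 fell and 7 did not pass (6 higher, 1 lower within the list). The mast cell list had a median log2 of 2.80 (camera adjusted p = 8.30e-09, or 0.0840 with an estimated correlation). For T and NK cell markers 1 of 22 members rose, 0 fell and 21 did not pass (1 higher, 0 lower within the list). The T and NK cell list had a median log2 of 1.12 (camera adjusted p = 7.34e-04, or 0.216 with an estimated correlation). Cd2, an adhesion molecule of lymphocytes, rose (log2 2.04 ± 0.32, adjusted p = 0.00152). For erythroid markers 0 of 4 members passed (3 higher, 0 lower within the list). The erythroid list had a median log2 of 3.03 (2.69 with groups at 0 set to the floor) (camera adjusted p = 0.00164, or 0.205 with an estimated correlation).

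Also between basal genotypes, among markers of small peritoneal macrophages, monocytes and dendritic cells 11 of 29 members rose, 0 fell and 18 did not pass (13 higher, 0 lower within the list). The list had a median log2 of 0.82 (camera adjusted p = 2.06e-12, or 0.0840 with an estimated correlation). Cd74, the invariant chain of MHC class II (log2 2.20 ± 0.29, adjusted p = 4.25e-04), Napsa, an aspartic protease gene (log2 2.74 ± 0.34, adjusted p = 2.31e-04), and Cd209a, a lectin of dendritic cells (log2 1.96 ± 0.30, adjusted p = 0.00131), were higher; B cells also express MHC class II genes. Scd1, a fatty acid desaturase gene, rose 11.5-fold (log2 3.52 ± 0.38, adjusted p = 9.40e-05), and Ly6a, the stem cell antigen Sca-1, rose 8.63-fold (log2 3.11 ± 0.37, adjusted p = 1.65e-04). Spp1, the gene of osteopontin, fell 25.7-fold (log2 -4.68 ± 0.62, adjusted p = 6.90e-04), and Gatm, the first enzyme of creatine synthesis, fell 7.29-fold (log2 -2.87 ± 0.28, adjusted p = 4.30e-05). Tpm3-rs7, a tropomyosin-related gene whose reads can be shared with paralogs, had the largest fitted rise by the naming rule (log2 5.26 ± 0.46, adjusted p = 2.83e-05). The test passed 303 genes as higher and 178 as lower, 481 in all, with 2057 at an unadjusted p under 0.05. Higher genes made up 63.0% of calls with TMM scaling and 79.3% with library totals, which moved the median of all genes to 0.13. There were 176 higher and 32 lower without knockout basal replicate 1, 174 and 48 without knockout basal replicate 2, 202 and 68 without wild-type basal replicate 2 and 195 and 213 without wild-type basal replicate 1. The majority turned without wild-type basal replicate 1, and with no filter (454 and 580).

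**Figure D2:**
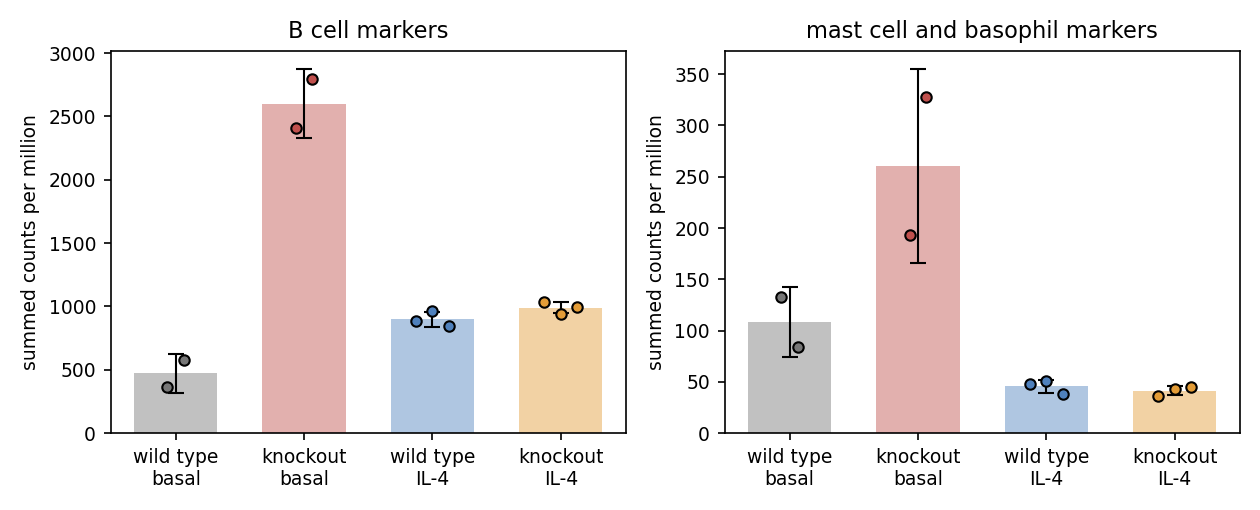
Summed CPM of B cell markers and of mast cell and basophil markers by group, with 1 point per library and bars for the mean ± SD. B cell markers average 2602 CPM in knockout basal libraries against 471 CPM in wild-type basal libraries, and mast cell markers 261 against 108 CPM.

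Under basal conditions, in the G2 and mitosis list 0 of 43 members rose, 5 fell and 38 did not pass (0 higher, 9 lower within the list). The mitosis list had a median log2 of -0.79 (camera adjusted p = 2.29e-08, or 0.205 with an estimated correlation). Spc25, a kinetochore gene, fell 3.19-fold (log2 -1.67 ± 0.28, adjusted p = 0.00243). In the S phase list 0 of 38 members rose, 2 fell and 36 did not pass (0 higher, 2 lower within the list). The S phase list had a median log2 of -0.37 (camera adjusted p = 8.30e-04, or 0.306 with an estimated correlation). For respiratory complexes I to IV 0 of 61 members rose, 2 fell and 59 did not pass (0 higher, 12 lower within the list). The respiratory complex list had a median log2 of -0.45 (camera adjusted p = 2.62e-07, or 0.496 with an estimated correlation). Ndufs4 of complex I fell (log2 -2.04 ± 0.38, adjusted p = 0.00705). For ATP synthase 0 of 16 members rose, 2 fell and 14 did not pass (0 higher, 9 lower within the list). The ATP synthase list had a median log2 of -0.71 (camera adjusted p = 4.15e-04, or 0.333 with an estimated correlation). Atpif1, an inhibitor of that enzyme, fell (log2 -1.27 ± 0.29, adjusted p = 0.0210). For glutathione and NRF2 targets 0 of 41 members rose, 1 fell and 40 did not pass (0 higher, 0 lower within the list). The glutathione list had a median log2 of -0.20 (camera adjusted p = 0.0277, or 0.602 with an estimated correlation). Ndufs4 lost its call without knockout basal replicate 2 (adjusted p = 0.0866), wild-type basal replicate 2 (0.0748) or knockout basal replicate 1 (0.0602). Atpif1 lost its call without wild-type basal replicate 2 (adjusted p = 0.239), knockout basal replicate 2 (0.134) or replicate 1 (0.122). The S phase list lost its call without knockout basal replicate 1 (camera adjusted p = 0.109). The glutathione list lost its call without wild-type basal replicate 1 (camera adjusted p = 0.0845), knockout basal replicate 1 (0.0534) or replicate 2 (0.0525).

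In the same comparison, for interferon-stimulated genes 1 of 51 members rose, 0 fell and 50 did not pass (1 higher, 0 lower within the list). The interferon list had a median log2 of -0.42 (camera adjusted p = 0.00534, or 0.140 with an estimated correlation). For endoplasmic reticulum stress 0 of 26 members passed (0 higher, 0 lower within the list). The list had a median log2 of -0.36 (camera adjusted p = 0.0136, or 0.140 with an estimated correlation). For ribosomal proteins 0 of 69 members rose, 1 fell and 68 did not pass (0 higher, 0 lower within the list). The ribosomal list had a median log2 of -0.24 (camera adjusted p = 0.00182, or 0.602 with an estimated correlation). For immediate early genes, which handling of cells can raise, 3 of 29 members rose, 0 fell and 26 did not pass (5 higher, 2 lower within the list). The immediate early list had a median log2 of 0.41 (camera adjusted p = 0.0436, or 0.397 with an estimated correlation). Among efferocytosis receptors 2 of 32 members rose, 0 fell and 30 did not pass (3 higher, 0 lower within the list), Stab1 with log2 1.28 ± 0.28, adjusted p = 0.0167. The efferocytosis list had a median log2 of 0.16 (camera adjusted p = 0.266). Among glutamine genes 2 of 34 members rose, 0 fell and 32 did not pass (3 higher, 0 lower within the list), the transporter Slc1a5 with log2 1.22 ± 0.31, adjusted p = 0.0368. The glutamine list had a median log2 of 0.24 (camera adjusted p = 0.0677). With library totals the calls of glutathione, thioredoxin and NRF2 targets and of immediate early and handling stress ended (camera adjusted p = 0.0543 and 0.0569). Of the 14 lists called here, the B cell list alone kept its call with an estimated correlation. Stab1 lost its call without wild-type basal replicate 1 (adjusted p = 0.111), knockout basal replicate 1 (0.0977) or replicate 2 (0.0738). Slc1a5 lost its call in 6 of the 10 fits without 1 library (adjusted p up to 0.291 without knockout basal replicate 2). The endoplasmic reticulum stress list lost its call without knockout basal replicate 2 (camera adjusted p = 0.0562). The ribosomal list lost its call without wild-type basal replicate 2 (camera adjusted p = 0.263). The immediate early list lost its call in 6 of the 10 fits without 1 library (camera adjusted p up to 0.358 without knockout basal replicate 1).

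Averaged over both treatments, Manf fell in knockout (log2 -0.87 ± 0.15, adjusted p = 0.00551), as did Nars, asparaginyl-tRNA synthetase (log2 -1.21 ± 0.21, adjusted p = 0.00455), Spp1 (log2 -2.35 ± 0.36, adjusted p = 0.00360) and Socs3, a feedback inhibitor of cytokine signals (log2 -0.84 ± 0.16, adjusted p = 0.00876). Selp rose (log2 0.78 ± 0.15, adjusted p = 0.00936), and so did Scd1 (log2 1.62 ± 0.23, adjusted p = 0.00150) and Ciita, the master regulator of MHC class II genes (log2 1.29 ± 0.23, adjusted p = 0.00582). Basal libraries carried part of these: after IL-4, knockout and wild-type means were 35.1 and 35.7 CPM for Spp1 and 55.7 and 41.0 for Ciita. Scd1 had log2 -0.28 ± 0.29, adjusted p = 0.709 there. Interactions were log2 4.66 ± 0.73, adjusted p = 0.00373 for Spp1 and log2 -3.80 ± 0.47, adjusted p = 5.93e-04 for Scd1. In the endoplasmic reticulum stress list 0 of 26 members rose, 5 fell and 21 did not pass (0 higher, 10 lower within the list). The endoplasmic reticulum stress list had a median log2 of -0.36 (camera adjusted p = 5.77e-06, or 0.0256 with an estimated correlation), a call that held. The B cell list held as well, as 18 of 22 members rose, 0 fell and 4 did not pass (20 higher, 0 lower within the list). The B cell list had a median log2 of 1.43 (camera adjusted p = 3.69e-43, or 0.0105 with an estimated correlation). Pax5 had log2 2.27 ± 0.24, adjusted p = 1.17e-04. Of respiratory complex genes 0 of 61 members rose, 1 fell and 60 did not pass (0 higher, 12 lower within the list). The respiratory complex list had a median log2 of -0.34 (camera adjusted p = 3.34e-09, or 0.704 with an estimated correlation). Of ATP synthase genes 0 of 16 members passed (0 higher, 6 lower within the list). The ATP synthase list had a median log2 of -0.47 (camera adjusted p = 5.39e-04, or 0.704 with an estimated correlation). Of glutathione and NRF2 targets 0 of 41 members rose, 3 fell and 38 did not pass (0 higher, 5 lower within the list). The glutathione list had a median log2 of -0.20 (camera adjusted p = 0.00182, or 0.704 with an estimated correlation).

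Of ribosomal proteins 1 of 69 members rose, 3 fell and 65 did not pass (1 higher, 3 lower within the list) on average. The ribosomal list had a median log2 of -0.28 (camera adjusted p = 5.04e-07, or 0.704 with an estimated correlation). Of markers of small peritoneal macrophages, monocytes and dendritic cells 6 of 29 members rose, 1 fell and 22 did not pass (11 higher, 1 lower within the list). The list had a median log2 of 0.37 (camera adjusted p = 6.40e-07, or 0.289 with an estimated correlation). Its member Lyz1, whose reads can be shared with Lyz2, had log2 2.19 ± 0.18, adjusted p = 2.27e-05. Of the lists called on average, the B cell, ATP synthase and small macrophage lists were called under basal conditions but not after IL-4. In all, 269 genes were higher and 195 lower in knockout (464 of 11614, with 2187 at an unadjusted p under 0.05). Higher genes made up 58.0% of calls with TMM and 71.2% with library totals. There were 138 higher and 59 lower without knockout basal replicate 1, 148 and 61 without knockout basal replicate 2, 166 and 79 without wild-type IL-4 replicate 3, 161 and 87 without wild-type IL-4 replicate 1, 205 and 95 without wild-type basal replicate 2 and 178 and 204 without wild-type basal replicate 1. The majority turned without wild-type basal replicate 1, and with no filter (418 and 516). The genotype effects under basal conditions and after IL-4 were uncorrelated across genes, which are not independent replicates (Pearson -0.02). Both comparisons called 16 genes in either direction, where independent calls would give 3.98. Of the 16, 7 had the same direction in both.

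IL-4 induced the classical genes of alternative activation in wild-type macrophages. Chil3 rose from 1.44 ± 0.0994 to 1709.9 ± 262 CPM (log2 10.20 ± 0.37, adjusted p = 1.51e-10; n = 2 and 3 libraries), and Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), the arginase that marks this state, rose 91.2-fold (log2 6.51 ± 0.39, adjusted p = 3.97e-07). Retnla, a secreted resistin-like protein gene, rose 12.1-fold (log2 3.60 ± 0.25, adjusted p = 9.69e-07), and the lectins Mgl2 (log2 4.12 ± 0.39, adjusted p = 3.86e-05) and Clec10a (log2 3.32 ± 0.28, adjusted p = 1.10e-05) rose as well. In the alternative activation list 13 of 35 members rose, 2 fell and 20 did not pass (18 higher, 2 lower within the list). The alternative activation list had a median log2 of 0.91 (camera adjusted p = 6.97e-22, or 0.0214 with an estimated correlation), a call that held. Apoe, the gene of apolipoprotein E, fell from 25535 ± 16786 to 3402 ± 494 CPM (log2 -2.91 ± 0.31, adjusted p = 1.52e-04). In the G2 and mitosis list 12 of 43 members rose, 0 fell and 31 did not pass (25 higher, 1 lower within the list). The mitosis list had a median log2 of 1.43 (camera adjusted p = 1.14e-15, or 0.0790 with an estimated correlation). Tpx2, a spindle factor (log2 2.80 ± 0.42, adjusted p = 0.00126), Ccnb2, a mitotic cyclin (log2 2.17 ± 0.34, adjusted p = 0.00196), and Cenpe, a kinetochore motor (log2 1.83 ± 0.30, adjusted p = 0.00249), rose. The test passed 379 genes as higher and 325 as lower, 704 in all, with 2475 at an unadjusted p under 0.05. Higher genes were 53.8% of calls with TMM and 65.3% with library totals. There were 189 higher and 113 lower without wild-type basal replicate 2, 201 and 139 without wild-type IL-4 replicate 2, 227 and 151 without wild-type IL-4 replicate 3, 230 and 169 without wild-type IL-4 replicate 1 and 169 and 244 without wild-type basal replicate 1. The majority turned without wild-type basal replicate 1, and with limma-voom (314 and 331) and no filter (563 and 646).

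In wild type, Il6, the interleukin-6 gene, rose 10.5-fold (log2 3.39 ± 0.45, adjusted p = 5.73e-04), and in the NF-kB list 7 of 34 members rose, 0 fell and 27 did not pass (10 higher, 1 lower within the list). The NF-kB list had a median log2 of 0.60 (camera adjusted p = 1.20e-04, or 0.0793 with an estimated correlation). Fos (log2 3.01 ± 0.31, adjusted p = 8.79e-05), Jun (log2 2.17 ± 0.24, adjusted p = 1.34e-04) and Egr1 (log2 2.54 ± 0.38, adjusted p = 0.00120), which respond to stimulation and to handling, rose, and in their list 9 of 29 members rose, 0 fell and 20 did not pass (9 higher, 0 lower within the list). The immediate early list had a median log2 of 0.80 (camera adjusted p = 8.15e-08, or 0.0493 with an estimated correlation). For interferon-stimulated genes 0 of 51 members rose, 9 fell and 42 did not pass (0 higher, 12 lower within the list). The interferon list had a median log2 of -0.48 (camera adjusted p = 1.20e-05, or 0.0493 with an estimated correlation). For respiratory complexes 0 of 61 members rose, 7 fell and 54 did not pass (0 higher, 13 lower within the list). A median log2 of -0.39 for the respiratory complex list came with camera adjusted p = 1.14e-05, or 0.403 with an estimated correlation. Ndufb9 of complex I fell (log2 -1.25 ± 0.23, adjusted p = 0.00558). For ATP synthase 0 of 16 members rose, 4 fell and 12 did not pass (1 higher, 8 lower within the list). The ATP synthase list had a median log2 of -0.52 (camera adjusted p = 0.00516, or 0.376 with an estimated correlation). For ribosomal proteins 0 of 69 members rose, 6 fell and 63 did not pass (0 higher, 13 lower within the list). The ribosomal list had a median log2 of -0.29 (camera adjusted p = 1.24e-05, or 0.403 with an estimated correlation). The ATP synthase list lost its call without wild-type basal replicate 2 (camera adjusted p = 0.124) or wild-type IL-4 replicate 2 (0.0591).

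Also in wild type, Ccr2, the chemokine receptor of recruited monocytes, rose 7.04-fold (log2 2.82 ± 0.31, adjusted p = 1.46e-04), Clec4a2, a lectin receptor of myeloid cells, rose (log2 2.70 ± 0.36, adjusted p = 6.06e-04), and among markers of small peritoneal macrophages, monocytes and dendritic cells 10 of 29 members rose, 1 fell and 18 did not pass (14 higher, 1 lower within the list). The small macrophage and monocyte list had a median log2 of 1.24 (camera adjusted p = 3.22e-12, or 0.0493 with an estimated correlation). Mast cell markers went from 108 ± 34.2 to 45.6 ± 6.24 CPM in sum, and 0 of 11 members rose, 3 fell and 8 did not pass (0 higher, 6 lower within the list). The mast cell list had a median log2 of -2.64 (-2.06 with groups at 0 set to the floor) (camera adjusted p = 7.66e-09, or 0.0493 with an estimated correlation). Cma1 had log2 -4.43 ± 0.54, adjusted p = 3.37e-04. B cell markers summed to 471 ± 152 and 898 ± 59.6 CPM, and 7 of 22 members rose, 0 fell and 15 did not pass (14 higher, 1 lower within the list). The B cell list had a median log2 of 0.89 (camera adjusted p = 9.75e-10, or 0.0793 with an estimated correlation). Neutrophil markers fell from 511 ± 47.9 to 433 ± 38.8 CPM in sum. Yet 3 of 13 members rose, 1 fell and 9 did not pass (6 higher, 1 lower within the list). The list median was log2 1.18 (camera adjusted p = 0.00126, or 0.251 with an estimated correlation). For large macrophage markers 1 of 32 members rose, 5 fell and 26 did not pass (1 higher, 7 lower within the list). Their list had a median log2 of -0.35 (camera adjusted p = 0.0472, or 0.376 with an estimated correlation). Tgfb2 of the transforming growth factor family fell (log2 -1.05 ± 0.18, adjusted p = 0.00286), and Cd163, a haemoglobin scavenger receptor, rose (log2 2.56 ± 0.32, adjusted p = 3.98e-04). The large macrophage call ended with library totals (camera adjusted p = 0.0642). Also called were fatty acid oxidation (3 of 31 higher, 0 lower, median log2 0.28, camera adjusted p = 0.0274, or 0.311 with an estimated correlation) and cholesterol synthesis (0 of 23 higher, 1 lower, median log2 -0.38, camera adjusted p = 0.0146, or 0.251 with an estimated correlation). Of 15 called lists, 5 held with an estimated correlation. The large macrophage list lost its call in 5 of the 10 fits without 1 library (camera adjusted p up to 0.287 without wild-type basal replicate 1). The fatty acid oxidation list lost its call without wild-type basal replicate 1 (camera adjusted p = 0.165) or wild-type IL-4 replicate 1 (0.0745). The cholesterol synthesis list lost its call without wild-type basal replicate 1 (camera adjusted p = 0.201).

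In knockout macrophages IL-4 raised Chil3, Arg1 and Retnla and a broad set of division genes. Chil3 rose from 1.37 ± 0.0454 to 402 ± 96.8 CPM (log2 8.18 ± 0.35, adjusted p = 1.68e-09), Arg1 rose 31.5-fold (log2 4.98 ± 0.36, adjusted p = 1.56e-06) and Retnla 26.0-fold (log2 4.70 ± 0.27, adjusted p = 6.91e-08). In the alternative activation list 13 of 35 members rose, 2 fell and 20 did not pass (18 higher, 5 lower within the list). The alternative activation list had a median log2 of 0.93 (camera adjusted p = 2.70e-15, or 0.0140 with an estimated correlation). In the G2 and mitosis list 38 of 43 members rose, 0 fell and 5 did not pass (41 higher, 1 lower within the list). The mitosis list had a median log2 of 2.91 (camera adjusted p = 1.06e-59, or 0.00354 with an estimated correlation). Hmmr, a spindle-associated gene (log2 5.13 ± 0.65, adjusted p = 3.43e-04), Tpx2 (log2 3.98 ± 0.45, adjusted p = 9.12e-05) and Cenpe (log2 3.39 ± 0.33, adjusted p = 2.34e-05) rose. In the S phase list 12 of 38 members rose, 0 fell and 26 did not pass (17 higher, 0 lower within the list). The S phase list had a median log2 of 1.17 (camera adjusted p = 3.05e-10, or 0.0583 with an estimated correlation). Clspn, a replication checkpoint gene, rose 9.67-fold (log2 3.27 ± 0.38, adjusted p = 9.33e-05). Ccdc80, an extracellular matrix gene, rose 58.7-fold (log2 5.87 ± 0.47, adjusted p = 1.98e-06), and Myh7, a myosin heavy chain gene, rose 44.4-fold (log2 5.47 ± 0.69, adjusted p = 2.40e-04). Cxcl13 fell from 1119 ± 325 to 49.7 ± 32.8 CPM (log2 -4.50 ± 0.43, adjusted p = 5.29e-05). The test passed 475 genes as higher and 408 as lower, 883 in all, with 2639 at an unadjusted p under 0.05. Higher genes were 53.8% of calls with TMM and 42.0% with library totals, which moved the median of all genes to -0.10. There were 164 higher and 163 lower without knockout basal replicate 2, 164 and 193 without knockout basal replicate 1 and 352 and 270 without knockout IL-4 replicate 3. The majority turned without knockout basal replicate 1, and with library totals (386 and 532) and limma-voom (380 and 425).

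In knockout, Apoe (log2 -2.37 ± 0.30, adjusted p = 3.02e-04), Apoc1, another apolipoprotein (log2 -2.78 ± 0.33, adjusted p = 1.32e-04), Pltp, a phospholipid transfer protein (log2 -1.52 ± 0.22, adjusted p = 5.36e-04), and Scd1 (log2 -2.70 ± 0.32, adjusted p = 9.58e-05) were lower after IL-4, and in the list of LXR targets 2 of 19 members rose, 5 fell and 12 did not pass (2 higher, 6 lower within the list). The LXR list had a median log2 of -0.37 (camera adjusted p = 0.00991, or 0.0921 with an estimated correlation). Stab1 fell (log2 -1.33 ± 0.25, adjusted p = 0.00390), and Cd63, a tetraspanin of late endosomes, fell (log2 -3.44 ± 0.30, adjusted p = 6.09e-06). B cell markers fell from 2602 ± 273 to 992 ± 46.0 CPM in sum, and 0 of 22 members rose, 19 fell and 3 did not pass (0 higher, 20 lower within the list). The B cell list had a median log2 of -1.98 (camera adjusted p = 1.09e-32, or 0.0140 with an estimated correlation). Cd79a, a chain of the B cell receptor, had log2 -2.45 ± 0.29, adjusted p = 9.58e-05. For mast cell markers 0 of 11 members rose, 9 fell and 2 did not pass (0 higher, 10 lower within the list). The mast cell list had a median log2 of -7.08 (-5.28 with groups at 0 set to the floor) (camera adjusted p = 9.10e-28, or 0.00952 with an estimated correlation). Mcpt4, a chymase gene with no counts after IL-4 in knockout, was at least 359-fold lower, and Cma1 had log2 -7.08 ± 0.53, adjusted p = 1.56e-06. For erythroid markers 0 of 4 members rose, 2 fell and 2 did not pass (0 higher, 3 lower within the list). The erythroid list had a median log2 of -3.44 (camera adjusted p = 0.0120, or 0.321 with an estimated correlation). For T and NK cell markers 0 of 22 members rose, 1 fell and 21 did not pass (0 higher, 1 lower within the list). The T and NK cell list had a median log2 of -1.64 (camera adjusted p = 2.41e-04, or 0.203 with an estimated correlation). Cd2 fell (log2 -2.0 ± 0.28, adjusted p = 3.73e-04). Also called were immediate early and handling stress (6 of 29 higher, 0 lower, median log2 0.37, camera adjusted p = 0.0176, or 0.321 with an estimated correlation) and ribosomal proteins (0 of 69 higher, 6 lower, median log2 -0.40, camera adjusted p = 6.82e-05, or 0.577 with an estimated correlation). Of 10 called lists, 4 held with an estimated correlation: alternative activation, G2 and mitosis, B cell, and mast cell and basophil markers. The immediate early list lost its call without knockout basal replicate 2 (camera adjusted p = 0.141) or knockout IL-4 replicate 2 (0.0951).

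Averaged over both genotypes, IL-4 raised Chil3 (log2 9.19 ± 0.26, adjusted p = 2.25e-12), Arg1 (log2 5.75 ± 0.27, adjusted p = 6.76e-09), Retnla (log2 4.15 ± 0.19, adjusted p = 1.57e-09) and Mgl2 (log2 3.70 ± 0.27, adjusted p = 9.81e-07), and in the alternative activation list 18 of 35 members rose, 2 fell and 15 did not pass (21 higher, 3 lower within the list). The alternative activation list had a median log2 of 0.98 (camera adjusted p = 9.27e-28, or 0.00529 with an estimated correlation). In the G2 and mitosis list 40 of 43 members rose, 1 fell and 2 did not pass (41 higher, 1 lower within the list). The mitosis list had a median log2 of 2.25 (camera adjusted p = 2.34e-54, or 0.00529 with an estimated correlation). In the S phase list 10 of 38 members rose, 0 fell and 28 did not pass (15 higher, 0 lower within the list). The S phase list had a median log2 of 0.57 (camera adjusted p = 1.33e-05, or 0.164 with an estimated correlation). Also called were mast cell (0 of 11 higher, 8 lower, median log2 -4.65 (-3.31 with groups at 0 set to the floor), camera adjusted p = 5.93e-25, or 0.0159 with an estimated correlation), large macrophage (3 of 32 higher, 11 lower, median log2 -0.15, camera adjusted p = 0.0208, or 0.329 with an estimated correlation), small macrophage and monocyte (10 of 29 higher, 3 lower, median log2 0.61, camera adjusted p = 5.58e-04, or 0.269 with an estimated correlation) and B cell (0 of 22 higher, 6 lower, median log2 -0.52, camera adjusted p = 0.00120, or 0.329 with an estimated correlation), the last raised in wild type and lowered in knockout. Of 15 called lists, 3 held: alternative activation, G2 and mitosis, and mast cell. Axl, a receptor for dying cells, rose (log2 1.28 ± 0.22, adjusted p = 0.00170), while C1qa, a complement component that coats them, fell (log2 -0.97 ± 0.16, adjusted p = 9.86e-04). Of 11614 genes, 817 rose and 676 fell (1493 in all, 3145 at an unadjusted p under 0.05). There were 475 higher and 366 lower without knockout basal replicate 2, 496 and 382 without knockout basal replicate 1, 548 and 421 without wild-type IL-4 replicate 2 and 575 and 442 without wild-type basal replicate 2. The IL-4 effects of the genotypes, which share no library, had a Pearson correlation of 0.246 and Spearman correlation of 0.232 across 11614 genes, which are not independent replicates. Calls in both genotypes numbered 113 up, 63 down and 35 opposite, where independence would give 15.5 up, 11.4 down and 26.6 opposite. The large macrophage list lost its call without knockout IL-4 replicate 2 (camera adjusted p = 0.102) or wild-type basal replicate 1 (0.0770).

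**Figure D3:**
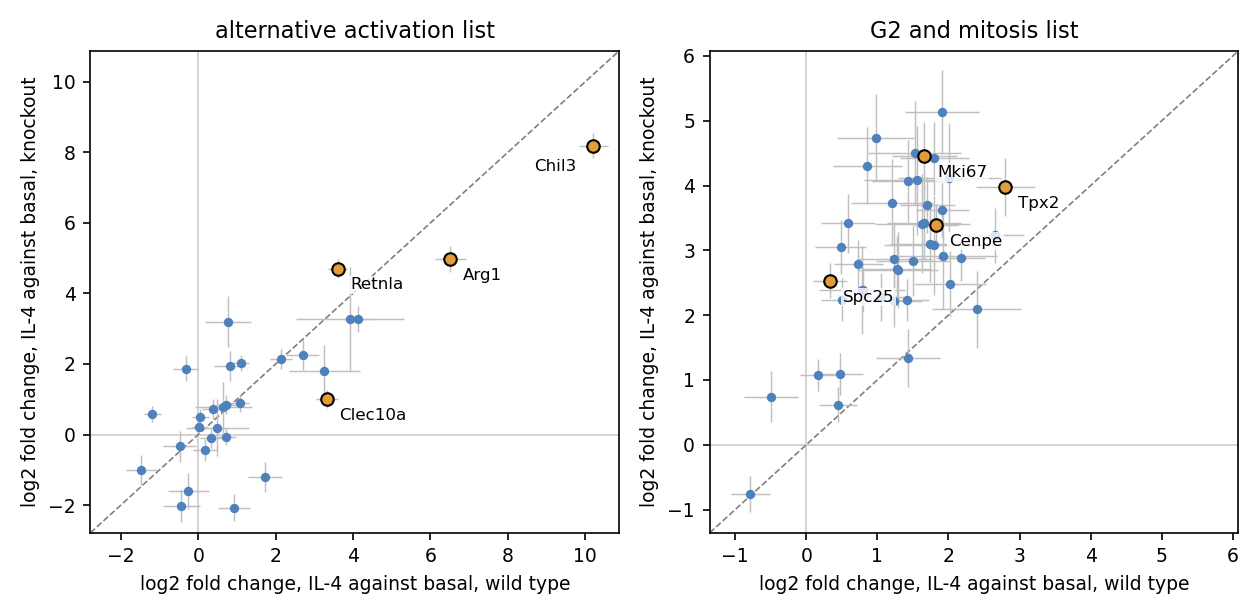
Log2 change from basal to IL-4 in wild type (x axis) and knockout (y axis) for members of the alternative activation list and of the G2 and mitosis list, with 1 point per gene, bars for the standard error and a dashed line of equal change. Members with a group at 0 counts are left out; the G2 and mitosis genes lie mostly above the line, with list medians of 1.43 in wild type and 2.91 in knockout.

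The interaction passed 326 genes, 119 with a term above 0 (IL-4 minus basal more positive in knockout) and 207 below. An unadjusted p was under 0.05 for 1778. Each term also holds the basal genotype difference, as in B cell RNA. Spc25 (log2 2.20 ± 0.35, adjusted p = 0.00287), Clspn (log2 2.63 ± 0.47, adjusted p = 0.00598) and Cep55, which acts in the last step of cell division (log2 4.71 ± 0.73, adjusted p = 0.00240), had positive terms. In the G2 and mitosis list 10 of 43 members had a called positive term, 0 a called negative term and 33 did not pass (19 higher, 0 lower within the list). A median log2 of 1.60 for the mitosis list came with camera adjusted p = 2.68e-19, or 0.0733 with an estimated correlation. Of alternative activation genes, Clec10a had a negative term (log2 -2.31 ± 0.36, adjusted p = 0.00227). So did the PD-1 ligand Pdcd1lg2 (log2 -2.98 ± 0.57, adjusted p = 0.00863), perhaps from B cell RNA. Ccl24's was positive (log2 1.76 ± 0.31, adjusted p = 0.00557). For genes of the averaged IL-4 response, the 817 raised genes had a median interaction of 0.10 (camera, no permutation test, p = 0.189). The 676 lowered genes had a median of 0.01 (camera, no permutation test, p = 0.359), and there the median and the test differ in sign. Raised genes passed, with a positive median, when chosen at an adjusted p under 0.01. Without 1 library the genotypes no longer have equal numbers of libraries. The choice of genes can then favour a sign of the interaction, so those fits do not decide. Interaction calls in the full fit were 33 positive and 27 negative for raised genes, and 11 and 41 for lowered genes. Positive terms were 36.5% of calls with TMM and 25.1% with library totals, which moved the median of all genes to -0.17. There were 45 positive and 137 negative without knockout basal replicate 1, 60 and 152 without wild-type IL-4 replicate 1, 75 and 146 without knockout basal replicate 2, 72 and 163 without wild-type IL-4 replicate 3, 71 and 172 without wild-type basal replicate 2 and 161 and 172 without wild-type basal replicate 1. The majority turned with no filter (487 and 332).

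Among other groups, 3 of 38 S phase members had a positive call, 0 a negative one and 35 did not pass (6 higher, 0 lower within the list). The S phase list had a median log2 of 1.03 (camera adjusted p = 6.71e-07, or 0.0941 with an estimated correlation). For efferocytosis receptors 0 of 32 members had a positive call, 2 a negative one and 30 did not pass (0 higher, 4 lower within the list). The efferocytosis list had a median log2 of -0.37 (camera adjusted p = 0.0339, or 0.185 with an estimated correlation). Stab1 had log2 -2.08 ± 0.36, adjusted p = 0.00488. In the glutamine list 0 of 34 members had a positive call, 1 a negative one and 33 did not pass (0 higher, 1 lower within the list). The glutamine list had a median log2 of -0.39 (camera adjusted p = 0.0435, or 0.410 with an estimated correlation). The called member was Slc1a5 (log2 -1.83 ± 0.40, adjusted p = 0.0193). For respiratory complexes 1 of 61 members had a positive call, 0 a negative one and 60 did not pass (1 higher, 0 lower within the list), with median log2 0.19, camera adjusted p = 0.0415, or 0.831 with an estimated correlation, and for ATP synthase 0 of 16 members passed (2 higher, 0 lower within the list). The ATP synthase list had a median log2 of 0.47 (camera adjusted p = 0.0339, or 0.573 with an estimated correlation). For interferon-stimulated genes 1 of 51 members had a positive call, 1 a negative one and 49 did not pass (2 higher, 1 lower within the list). The interferon list had a median log2 of 0.67 (camera adjusted p = 3.15e-04, or 0.0733 with an estimated correlation). Ly6a had log2 -3.53 ± 0.46, adjusted p = 8.29e-04. The glutamine and respiratory complex calls ended with library totals (camera adjusted p = 0.0584 and 0.102). Slc1a5 lost its call in 4 of the 10 fits without 1 library (adjusted p up to 0.123 without knockout basal replicate 2). The efferocytosis list lost its call without wild-type basal replicate 2 (camera adjusted p = 0.261), knockout IL-4 replicate 1 (0.0676) or knockout basal replicate 2 (0.0523). The glutamine list lost its call in 6 of the 10 fits without 1 library (camera adjusted p up to 0.239 without wild-type basal replicate 2). The respiratory complex list lost its call in 6 of the 10 fits without 1 library (camera adjusted p up to 0.305 without wild-type IL-4 replicate 2). The ATP synthase list lost its call in 5 of the 10 fits without 1 library (camera adjusted p up to 0.194 without wild-type basal replicate 2).

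For cell type markers, in the B cell list 0 of 22 members had a positive call, 18 a negative one and 4 did not pass (0 higher, 19 lower within the list). The B cell list had a median log2 of -3.10 (camera adjusted p = 1.47e-52, or 0.00717 with an estimated correlation), the single list call that held. Cd79a had log2 -3.43 ± 0.42, adjusted p = 5.93e-04 and Ebf1 log2 -3.73 ± 0.36, adjusted p = 7.19e-05. For small peritoneal macrophage, monocyte and dendritic cell markers 0 of 29 members had a positive call, 8 a negative one and 21 did not pass (0 higher, 13 lower within the list). The small macrophage and monocyte list had a median log2 of -0.95 (camera adjusted p = 2.54e-11, or 0.0733 with an estimated correlation). Cd74 had log2 -2.44 ± 0.37, adjusted p = 0.00197. For neutrophil markers 0 of 13 members had a positive call, 3 a negative one and 10 did not pass (0 higher, 3 lower within the list). The neutrophil list had a median log2 of -1.68 (camera adjusted p = 2.22e-05, or 0.0941 with an estimated correlation). For mast cell and basophil markers 0 of 11 members had a positive call, 2 a negative one and 9 did not pass (0 higher, 6 lower within the list). The mast cell list had a median log2 of -3.78 (-3.60 with groups at 0 set to the floor) (camera adjusted p = 1.21e-05, or 0.0941 with an estimated correlation). For T and NK cell markers 0 of 22 members had a positive call, 1 a negative one and 21 did not pass (0 higher, 2 lower within the list). The T and NK cell list had a median log2 of -1.91 (-1.98 with groups at 0 set to the floor) (camera adjusted p = 2.22e-05, or 0.0941 with an estimated correlation). For erythroid markers 0 of 4 members had a positive call, 1 a negative one and 3 did not pass (0 higher, 2 lower within the list). The erythroid list had a median log2 of -4.52 (-3.71 with groups at 0 set to the floor) (camera adjusted p = 1.52e-04, or 0.0941 with an estimated correlation). For immediate early genes 0 of 29 members had a positive call, 1 a negative one and 28 did not pass (1 higher, 4 lower within the list). The immediate early list had a median log2 of -0.40 (-0.39 with groups at 0 set to the floor) (camera adjusted p = 0.0435, or 0.341 with an estimated correlation), and the call of immediate early and handling stress ended with library totals (camera adjusted p = 0.0584). The immediate early list lost its call in 7 of the 10 fits without 1 library (camera adjusted p up to 0.341 without knockout basal replicate 1).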

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

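Tests chosen only after the result was seen were the comparison of B cell, mesothelial and neutrophil medians, and the B cell test of the mitosis pattern; the others were set before.

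The interaction of genotype and IL-4, which also takes in the basal genotype difference, passed 326 genes. The largest positive terms by the naming rule were Myh7 4.78, Cep55 4.71, Kif14 4.69, Spp1 4.66, Eif3j2 4.53, Clec5a 4.41, Gatm 4.15, Ccdc80 4.12, Knl1 3.77 and Nusap1 3.45. The largest negative terms were Fkbp5 -5.46, Edaradd -5.05, Tpm3-rs7 -4.92, Kcna3 -4.50, B3gnt5 -4.42, Crispld2 -4.32, Fcrl5 -4.29, Mmp8 -4.21 and Cacna1i -4.19, and Mcpt4, with no counts in the knockout IL-4 libraries, was bounded at -5.70. Myh7 lost its call without knockout basal replicate 1 (adjusted p = 0.0501). Kif14 lost its call without wild-type basal replicate 2 (adjusted p = 0.114), knockout basal replicate 2 (0.0851) or wild-type IL-4 replicate 1 (0.0548). Clec5a lost its call without knockout basal replicate 2 (adjusted p = 0.108) or replicate 1 (0.0851). Knl1 lost its call in 4 of the 10 fits without 1 library (adjusted p up to 0.150 without wild-type basal replicate 2). Nusap1 lost its call without wild-type basal replicate 2 (adjusted p = 0.0868) or replicate 1 (0.0519). Mcpt4 lost its call in 4 of the 10 fits without 1 library (adjusted p up to 0.0771 without wild-type basal replicate 2). Edaradd lost its call without knockout basal replicate 2 (adjusted p = 0.0533), as did Mmp8 (0.0705). Kcna3 lost its call without wild-type basal replicate 2 (adjusted p = 0.0634). Reads of Eif3j2 and Tpm3-rs7 can be shared with paralogs. Median terms of the lists called by the same test were 1.03 for S phase and DNA replication, 1.60 for G2 and mitosis, -0.37 for efferocytosis receptors and bridging molecules, -0.39 for glutamine use and transamination, 0.19 for respiratory complexes, 0.47 for ATP synthase, 0.67 for interferon-stimulated genes, -0.95 for small peritoneal macrophage and monocyte and dendritic cell markers, -3.10 for B cell markers, -1.91 for T and NK cell markers, -1.68 for neutrophil markers, -3.78 for mast cell and basophil markers, -4.52 for erythroid markers and -0.40 for immediate early and handling stress. With groups at 0 at the floor, medians were -1.98 for T and NK cell, -3.60 for mast cell, -3.71 for erythroid and -0.39 for immediate early genes. Of the 14 lists, only the B cell list held its call with an estimated correlation.

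B cell markers were higher in knockout than wild type under basal conditions, although the sort on CD64, ICAM-2 and CD115 would remove B cells. A second list of 19 B cell genes, none on the fixed list and written down before its test, had a median log2 of 1.69, with 18 members above 0, 7 passing as higher and 1 as lower. The last, Cd24a, named after its values were seen, was the most abundant (659 CPM in wild type, 275 CPM in knockout). It peaked where B cell markers were lowest, so it decides little. B cells or their RNA remain a candidate explanation. Wild-type basal libraries held at least 10 CPM of 8 of those genes and of 9 of the 22 fixed ones; Cd79a stood at 159 CPM in knockout and 18.5 CPM in wild type. Library totals (fixed list median 3.19) lie too near TMM to test scaling. Against a lower macrophage share that raised every other cell type alike, the B cell median lay 3.66 above mesothelial and 2.31 above neutrophil medians. Medians of mast cell (2.80) and erythroid markers (2.69 with groups at 0 set to the floor, 4 genes) lay near the B cell median of 3.03, with T and NK cell markers at 1.12 and eosinophil markers at 0.48, so the entry of several of these cell types together stays open. An effect of the genotype on B cells or on the sort stays open and was not tested.

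The G2 and mitosis list was higher in knockout than wild type after IL-4, with a median log2 of 0.75. Knockout IL-4 replicate 3 alone is argued against by a median of 0.63 without it (range 0.63 to 0.78 without 1 IL-4 library). So are more B cells in knockout libraries by the B cell median of -0.15. Scaling (lowest median 0.71) varied too little to test. The adjusted p of 0.254 with an estimated correlation ends the list call, so more division of knockout macrophages after IL-4 may stand only as a hypothesis, which DNA content of the sorted macrophages could test.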

How the results depend on the processing

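Chosen only after the data were seen were the fit with a B cell index as covariate and the replicate block joined to an estimated correlation; all other settings were set beforehand. The direction of each named value held under every setting run that was set beforehand. Named values that lost their call numbered 8 with DESeq2 size factors, 25 with library totals, 2 with the DESeq2 test, 61 with limma-voom, 7 with no filter, 1 with a mean of 10 counts, 7 without robust dispersion, 40 with only the groups compared and 85 with the replicate block.

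Calls moved by more than 1.5 times with the DESeq2 test to 366 (genotype after IL-4), 848 (basal genotype), 805 (averaged genotype), 1109 (wild-type IL-4) and 600 (interaction), and with no filter to 505 (genotype after IL-4), 1034 (basal genotype), 934 (averaged genotype), 1209 (wild-type IL-4), 1423 (knockout IL-4) and 819 (interaction); the cause was not tested. A threshold of at least 2-fold left 222 (averaged genotype) and 631 (averaged IL-4) by its construction. With the replicate block, which uses degrees of freedom, calls were 554 (knockout IL-4) and 836 (averaged IL-4). Replicate numbers did not pair the libraries: correlations of deviations within 13 pairs of equal number ran from -0.110 to 0.0620, and 0 of 10 libraries matched best with their own number.

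Without 1 library, calls ranged from 21 to 129 (genotype after IL-4), 208 to 550 (basal genotype), 197 to 441 (averaged genotype), 302 to 764 (wild-type IL-4), 327 to 931 (knockout IL-4), 841 to 1560 (averaged IL-4) and 182 to 397 (interaction). Called lists ranged from 5 to 9 (genotype after IL-4), 12 to 14 (basal genotype), 7 to 9 (averaged genotype), 13 to 16 (wild-type IL-4), 9 to 12 (knockout IL-4), 11 to 16 (averaged IL-4) and 9 to 15 (interaction). With an estimated correlation the called lists were 0 (genotype after IL-4), 1 (basal genotype), 2 (averaged genotype), 5 (wild-type IL-4), 4 (knockout IL-4), 3 (averaged IL-4) and 1 (interaction), with fry 3 (genotype after IL-4) and 4 (averaged genotype), and with the replicate block and an estimated correlation 0 (genotype after IL-4), 1 (basal genotype), 1 (averaged genotype), 1 (wild-type IL-4), 4 (knockout IL-4), 3 (averaged IL-4) and 1 (interaction); the cause was not tested.

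For genes raised by IL-4 on average, with p from camera and no permutation, the median interaction was 0.11 (p = 0.0109) when they were chosen at an adjusted p under 0.01. It ran from -0.0791 to 0.31 without 1 library. The median was 0.31 and 0.20 without knockout basal replicates 1 and 2, and 0.22 without knockout IL-4 replicate 2. Without wild-type basal replicates 1 and 2 it was -0.0791 and -0.0712. For lowered genes it ran from -0.15 to 0.22. There it was -0.09 and -0.15 without knockout basal replicates 1 and 2, and 0.22 and 0.03 without wild-type basal replicates 1 and 2. Each such fit chose its genes anew, with unequal numbers of libraries between genotypes. That choice can favour a sign of the interaction, so these medians do not test it. The Pearson correlation of the IL-4 effects was 0.388 at 50 CPM or more, and 0.175 to 0.254 without 1 library.

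The B cell index left 3 (basal genotype), 3 (averaged genotype), 39 (wild-type IL-4), 2 (knockout IL-4), 154 (averaged IL-4) and 2 (interaction) calls, and 81 for genotype after IL-4. Between groups lay 97.1% of its variance, so it was nearly collinear with the groups and that fit cannot part B cells from genotype. Of 547 called named values, 83 stayed called and 58 changed sign, of which 0 were called (smallest adjusted p = 0.606).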

Other observations

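The tests of this part were set before their results were seen. Averaged over both genotypes, Cpt1a, the entry enzyme of fatty acid oxidation, rose (log2 0.97 ± 0.18, adjusted p = 0.00219), as did Eci2, an isomerase of the same pathway (log2 1.45 ± 0.27, adjusted p = 0.00295), and in that list 7 of 31 members rose, 0 fell and 24 did not pass (9 higher, 0 lower within the list). The fatty acid oxidation list had a median log2 of 0.26 (camera adjusted p = 0.0297, or 0.317 with an estimated correlation). Apoe (log2 -2.64 ± 0.21, adjusted p = 4.15e-06) and Apoc1 (log2 -1.64 ± 0.23, adjusted p = 3.37e-04) fell, and for LXR targets 2 of 19 members rose, 4 fell and 13 did not pass (2 higher, 4 lower within the list). The LXR list had a median log2 of -0.26 (camera adjusted p = 0.0267, or 0.164 with an estimated correlation). For cholesterol synthesis 0 of 23 members rose, 2 fell and 21 did not pass (0 higher, 2 lower within the list). The cholesterol synthesis list had a median log2 of -0.33 (camera adjusted p = 0.0432, or 0.317 with an estimated correlation). The fatty acid oxidation list lost its call without wild-type basal replicate 1 (camera adjusted p = 0.0942), knockout basal replicate 1 (0.0832) or wild-type IL-4 replicate 1 (0.0582). The LXR list lost its call without knockout IL-4 replicate 2 (camera adjusted p = 0.0508) or wild-type IL-4 replicate 1 (0.0502). The cholesterol synthesis list lost its call in 4 of the 10 fits without 1 library (camera adjusted p up to 0.145 without wild-type basal replicate 1).

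Averaged over genotypes, ribosomal protein Rps14 fell (log2 -1.07 ± 0.17, adjusted p = 8.02e-04), and in its list 0 of 69 members rose, 19 fell and 50 did not pass (0 higher, 24 lower within the list). The ribosomal list had a median log2 of -0.33 (camera adjusted p = 1.94e-07, or 0.374 with an estimated correlation). Bst2, an antiviral tether, fell (log2 -1.17 ± 0.26, adjusted p = 0.00803), and among interferon-stimulated genes 1 of 51 members rose, 10 fell and 40 did not pass (1 higher, 16 lower within the list). The interferon list had a median log2 of -0.26 (camera adjusted p = 0.0208, or 0.204 with an estimated correlation). Among immediate early genes 9 of 29 members rose, 0 fell and 20 did not pass (10 higher, 1 lower within the list) (median log2 0.40, camera adjusted p = 1.85e-06, or 0.0823 with an estimated correlation). Among NF-kB genes 11 of 34 members rose, 2 fell and 21 did not pass (14 higher, 2 lower within the list) (median log2 0.17, camera adjusted p = 7.74e-04, or 0.164 with an estimated correlation). Among respiratory complex genes 0 of 61 members rose, 9 fell and 52 did not pass (0 higher, 9 lower within the list) (median log2 -0.21, camera adjusted p = 5.58e-04, or 0.608 with an estimated correlation). The interferon list lost its call without knockout IL-4 replicate 2 (camera adjusted p = 0.0602).

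Of the 34 tested lists, 11 were called in no contrast. Beside those given for the genotype effect after IL-4, they were, in the averaged IL-4 contrast, ATF4 and amino-acid response (median log2 0.12, camera adjusted p = 0.408), HIF1 and hypoxia targets (median log2 -0.10, camera adjusted p = 0.936), actin remodelling and phagocytic cup (median log2 0.18, camera adjusted p = 0.164), lysosome and autophagy (median log2 0.10, camera adjusted p = 0.694), eosinophil markers (median log2 0.27, camera adjusted p = 0.0834), mesothelial and fibroblast markers (median log2 -0.44, camera adjusted p = 0.543) and p53 targets and apoptosis (median log2 0.22, camera adjusted p = 0.121). The median, mean and test of a list differed in sign for 5 (genotype after IL-4), 5 (basal genotype), 6 (averaged genotype), 0 (wild-type IL-4), 6 (knockout IL-4), 2 (averaged IL-4) and 7 (interaction) lists, none of them called.

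Among the 10 splits of the IL-4 libraries, none but the real one called as many genes (96, highest other 3), and these splits are too few for a share under 0.05. No other split matched the real one in 60 within treatment for the averaged genotype effect (464, highest other 326). None did in 100 within genotype for averaged IL-4 (1493, highest other 88). This argues against chance, not mouse differences. The split that called 326 genes exchanged the genotype labels of the basal libraries, which turns the average into the interaction.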
